A study of Mus musculus with 16 samples.

How the data were processed

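The data were read counts per gene from liver and heart of 8 female C57BL/6J mice, 4 wild type (WT) and 4 quadruple knockouts (QKO), making 16 libraries in 4 groups of 4. Per the labels, total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced in pairs of 75 bp reads, with a stated depth of about 75 M reads. The authors' processing notes name mm10, CASAVA, bcl2fastq, FastQC, cutadapt, HISAT2, featureCounts and limma, with no versions. The deposited values were raw counts, whole numbers for 48709 Ensembl gene identifiers with versions. Neither the annotation release nor the strand setting of the counting was stated.

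Gene symbols, types and positions came from GENCODE release M21 on the mouse assembly GRCm38, the same assembly as mm10. Of the identifiers, 48349 matched it without the version, 41341 of them with the same version, and 360 did not match. All 16 columns of the table were mapped to a library by the labels, and 0 were left over. Checks of the strand gave no clear answer. Rn7sk and an unmatched identifier had equal counts in all 16 libraries, but the position and strand of the latter were not known. Gm42418, a ribosomal RNA locus, and CT010467.1 on the opposite strand had counts in a ratio of 0.897 to 0.918 in heart. Values of genes that overlap on opposite strands, such as Myh7 and Mhrt, could not be assumed to be free of shared reads.

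Total counts ran from 37.9 M to 67.9 M in liver and from 42.1 M to 72.6 M in heart. Protein-coding genes took 21.6 M to 40.7 M of them in liver and 7.71 M to 28.1 M in heart, so precision differed most between heart libraries. Count rates (CPM, counts per 1 M counts of a library) were computed on library sizes scaled by the trimmed mean of M-values (TMM). Values are given as mean and standard deviation (SD) over 4 animals. The text gives log2 fold changes of QKO over WT with their standard error (SE), which was the size of the fold change divided by the square root of the F statistic. Intervals of ratios of summed counts were 95% exact binomial intervals and cover counting error only.

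The replicate labels were checked for pairing. Within each tissue the same replicate number in WT and QKO did not in general mark similar samples, replicate 4 in heart excepted. Correlations across genes, which are not independent replicates, were taken after removal of group means. They were 0.0460, -0.0507, -0.0687 and 0.121 in liver, and 0.0807, 0.0945, 0.00525 and 0.331 in heart. The replicate number also follows the animal series, which is described below. Liver and heart of the same animal correlated at 0.0144 to 0.0965 in the 8 animals. The WT against QKO tests were therefore unpaired, and the test between tissues was also run with the animal as a block. Among the 24 pairs of replicates within groups none was a copy of the other, as the chi-square per gene was 26.3 or higher.

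Each tissue was tested apart with the quasi-likelihood F test of edgeR 4.0.16 under R 4.3.3, after the edgeR expression filter by group. The difference between tissues was the interaction of genotype and tissue in a fit of the 4 groups over 16 libraries. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The 4 Msr genes were also compared by a two-sided exact permutation test over the 70 relabellings of 4 against 4 animals. Before the data were examined, 58 gene lists were fixed, of pathways, cell types, the Msr genes and technical checks. Pathway and cell type lists with 3 or more tested members were compared with all other genes by camera of limma 3.58.1. The correlation between genes was preset at 0.01. The same test was run with the correlation estimated from the data, and fry was run as a rotation test. List members were also adjusted over the list alone.

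Genes were named by a rule fixed before the data were examined. It took the 4 Msr genes and, per tissue, the 8 largest rises and 8 largest falls past the threshold, with a mean CPM of 1 or more in the higher group and no overlap between WT and QKO libraries. Gene models without a proper name were left out of that ranking. It also took up to 3 members per list past the threshold, up to 5 genes per direction for the difference between tissues, up to 10 genes called in both tissues, and Nnt as a strain check. Any other gene was named after its values were seen: list members past the threshold over their list alone, called genes outside the rule, neighbours, paralogs and muscle genes.

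Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 4 libraries and a test against a fold of 1.3. Further ones were library sizes without the 20 most abundant genes, each replicate left out in turn, the replicate number as a block, the animal number series as a term, all 16 libraries in 1 fit, and the genes within 20 Mb of an Msr gene left out. Protein-coding genes alone, a robust dispersion, the share of nuclear ribosomal RNA as a covariate and the omission of libraries with unusual content were added after seeing the data. For the gene lists, the scaling alternatives and the animal number series were also added after seeing the data. The animal number series is the first digits of the animal number, 47 or 48, with 2 animals of each genotype in each; the labels do not say what it stands for.

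The procedure was tested on simulated data of the same size, in which 200 genes were changed. In liver 1.49% of genes changed by a fold of 1.5 were recovered, 40.3% at a fold of 2 and 87.9% at a fold of 4, and 12 of 98 calls were false. In heart these shares were 52.2%, 59.7% and 98.5%, with 7 of 147 calls false. For the difference between tissues they were 7.46%, 17.9% and 65.2%, with 0 of 60 calls false. A simulated shift of the unfolded protein response list by a fold of 1.3 gave a camera adjusted p of 1.033e-17 in liver and 2.507e-40 in heart. Genes were drawn independently of each other there. The simulation therefore does not show how camera with the preset correlation behaves when genes of a list are correlated.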

Results

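Methionine sulfoxide reductases return oxidised methionine in proteins to methionine, and in the mouse they are encoded by Msra, Msrb1, Msrb2 and Msrb3. RNA was measured in liver and heart of 8 female mice aged 3 to 6 months, 4 WT and 4 QKO animals in which all of these genes had been targeted. Both tissues came from the same animals, so each of the 4 groups had 4 libraries. Total counts per library were 37.9 M to 67.9 M in liver and 42.1 M to 72.6 M in heart. Xist, the RNA of the inactive X chromosome, had 3311 counts or more in every library, and Y-linked genes had 0 to 3 counts.

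The heart libraries differed in content. Nuclear ribosomal RNA loci took 33.5% to 60.2% of the count in 6 heart libraries, but 7.87% in WT heart 4 and 0.148% in QKO heart 4, against 0.0802% to 0.226% in liver. Transcripts of hepatocytes reached 276 to 1228 CPM of the protein-coding count in heart. Transcripts of pancreatic acinar cells reached 1602 CPM in WT liver 3 and 478 in WT liver 4, against 7.44 to 14.04 in the other liver libraries. WT liver 4 also held 652 CPM of skeletal muscle and 920 CPM of cardiomyocyte transcripts.

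**Figure D1:**
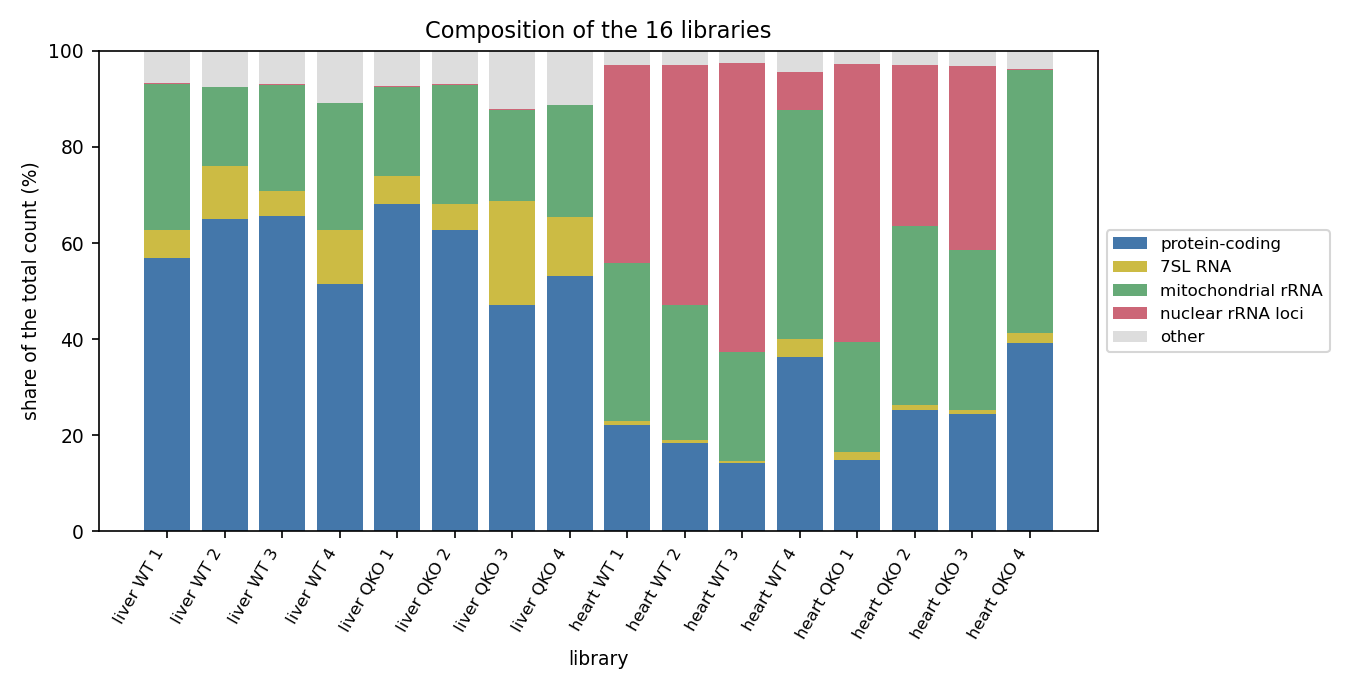
Share of the total count (percent) taken by protein-coding genes, 7SL RNA, mitochondrial ribosomal RNA, nuclear ribosomal RNA loci and all other genes in each of the 16 libraries, as stacked bars. The bars of WT heart 4 and QKO heart 4 hold 7.87% and 0.148% of nuclear ribosomal RNA, where the other heart libraries hold 33.5% or more.

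The first question was what was left of the RNA of the 4 targeted genes. Msrb2, the mitochondrial enzyme, was nearly absent from QKO animals. It fell from 6.10 ± 2.07 CPM to 0.0401 ± 0.0275 CPM in liver and from 9.48 ± 0.818 CPM to 0.118 ± 0.0363 CPM in heart (SD, n = 4), which left 0.657% and 1.24% of the WT level. Msrb3, an enzyme of the endoplasmic reticulum and mitochondria, kept 25.1% in liver and 16.3% in heart, where it fell from 35.4 ± 1.15 to 5.76 ± 0.421 CPM. The RNA of Msra, which repairs the S form of methionine sulfoxide, kept 60.7% in liver and 69.3% in heart. Msrb1, the selenoprotein of the family, kept 76.4% in liver and rose to 138% of the WT level in heart, from 11.1 ± 0.712 to 15.4 ± 1.51 CPM.

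In the edgeR test the log2 change of Msrb2 was -7.04 (SE 0.44, adjusted p = 2.874e-05) in liver and -6.40 (SE 0.17, adjusted p = 4.707e-11) in heart. For Msrb3 it was -1.99 (SE 0.20, adjusted p = 0.00194) and -2.62 (SE 0.07, adjusted p = 4.707e-11). Msra passed the threshold in heart, with -0.52 (SE 0.09, adjusted p = 0.0263), and not in liver, with -0.72 (SE 0.12, adjusted p = 0.0867). Msrb1 passed it in heart, with 0.48 (SE 0.08, adjusted p = 0.0337), and not in liver, with -0.39 (SE 0.18, adjusted p = 1.00). None of the 4 genes passed the interaction test between the tissues, where Msrb1 came nearest with a heart effect minus liver effect of 0.86 (SE 0.21, adjusted p = 0.851). The exact permutation p was 0.0286, the smallest that 70 relabellings can give, in all comparisons except Msrb1 in liver, where it was 0.114. The call of Msra in heart ended without each library except WT 4 (adjusted p up to 0.123), and that of Msrb1 without each library except QKO 1 (adjusted p up to 0.127). In the fit of all 16 libraries the adjusted p was 0.0781 for Msra and 0.996 for Msrb1 in heart.

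The genes are Msra (ENSMUSG00000054733.9, chromosome 14, 64122625 to 64455903 on GRCm38), Msrb1 (ENSMUSG00000075705.12, chromosome 17, 24736642 to 24742778), Msrb2 (ENSMUSG00000023094.14, chromosome 2, 19371440 to 19394976) and Msrb3 (ENSMUSG00000051236.13, chromosome 10, 120781096 to 120899101). Counts covered whole genes, so RNA that lacked a targeted exon was counted with the rest. Nnt, a mitochondrial transhydrogenase that is truncated in C57BL/6J, had log2 changes of -0.14 (SE 0.14) in liver and 0.03 (SE 0.07) in heart, and neither passed the threshold.

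**Figure D2:**
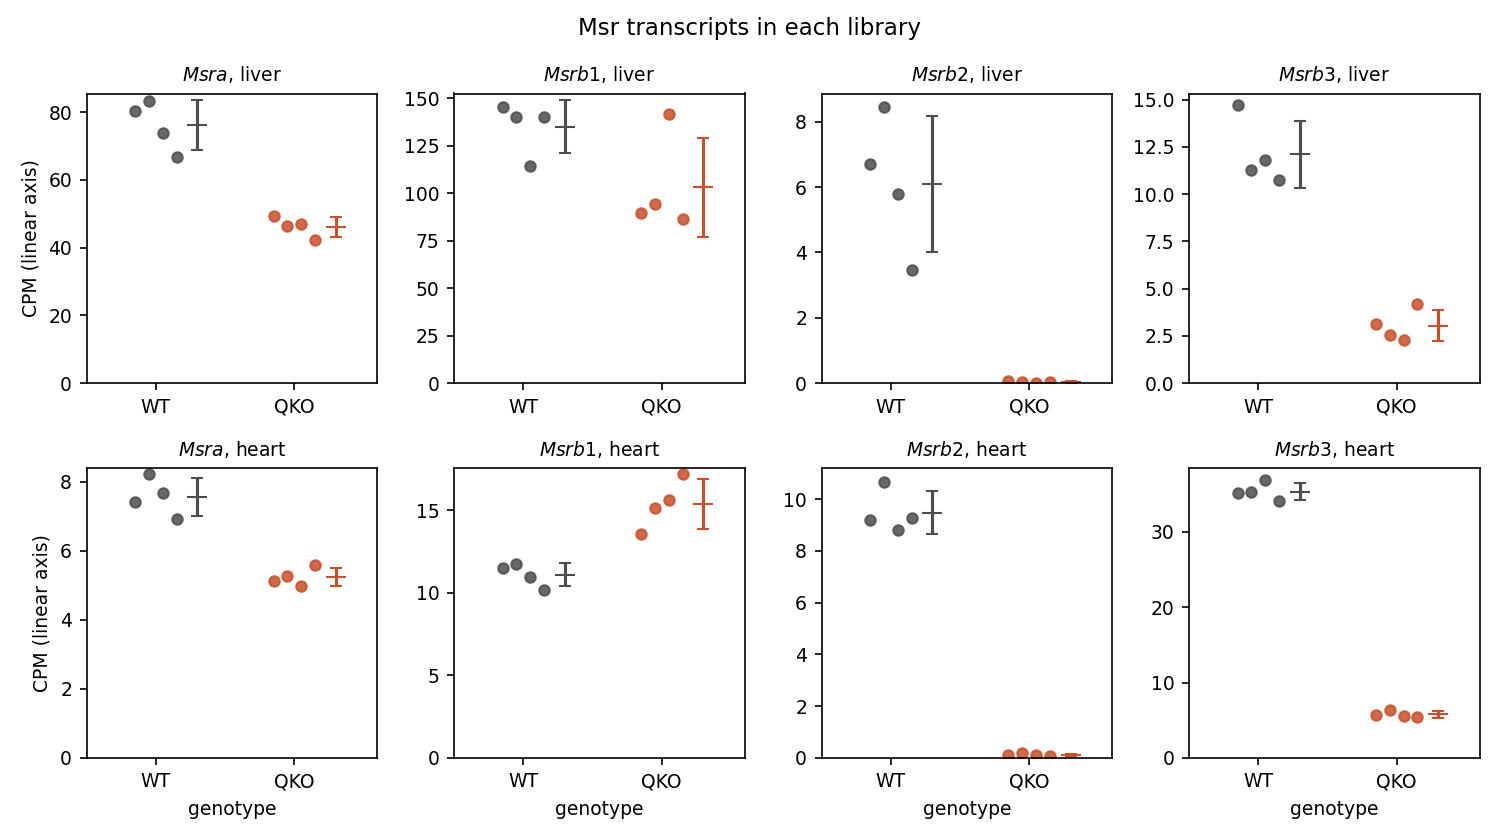
CPM (linear axis from 0) of Msra, Msrb1, Msrb2 and Msrb3 in WT and QKO libraries of liver and heart. Points are libraries and the horizontal marks with bars are mean ± SD of 4; Msrb2 lies near 0 in QKO, at 0.0401 CPM in liver and 0.118 CPM in heart, while Msra and Msrb1 keep 60.7% or more.

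The second question was which liver genes differed in QKO mice. Among the largest rises were Sult2a6 and Sult2a4, hydroxysteroid sulfotransferases of the liver. Sult2a6 rose from 0.0475 ± 0.0533 to 14.5 ± 9.92 CPM, and Sult2a4 from 0.447 ± 0.141 to 7.55 ± 4.55 CPM (SD, n = 4). Gdpd3, a lysophospholipase D that acts on lysophospholipids, rose 16.6-fold, from 0.349 ± 0.0526 to 5.87 ± 1.67 CPM. Ide, the protease that degrades insulin, fell from 89.6 ± 14.7 to 38.6 ± 3.33 CPM. Cebpe, a transcription factor of granulocytes, fell from 328 counts summed over the WT livers to 1 count in QKO.

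Of 17738 genes tested in liver, 15 passed the threshold, 10 higher and 5 lower in QKO, and 583 had an unadjusted p under 0.05 where chance would give 887. The log2 change was 8.11 for Sult2a6 (SE 0.67, adjusted p = 2.972e-04), 4.11 for Sult2a4 (SE 0.41, adjusted p = 0.00190), 4.05 for Gdpd3 (SE 0.26, adjusted p = 2.874e-05) and -1.21 for Ide (SE 0.15, adjusted p = 0.00615). The 6 other genes of the Sult2a family had log2 changes of -0.90 (Sult2a7) to 0.80 (Sult2a5), and none passed. Dab1, the adaptor of the reelin receptors, rose from 0.0904 ± 0.0466 to 1.35 ± 0.467 CPM (log2 3.86, SE 0.45, adjusted p = 0.00468). H2-T3, a nonclassical class I histocompatibility gene, had 3 counts over the WT livers and 319 in QKO, a ratio of 103 (95% counting interval 34.9 to 502, adjusted p = 0.0113). For Cebpe the ratio of WT over QKO was 339 (95% counting interval 60.4 to 13418, adjusted p = 0.00238). Mir686, a microRNA gene that lies inside the proteasome gene Psmb5, fell by 1.07 on the log2 scale (SE 0.14, adjusted p = 0.0128), beside a value of -0.76 for Psmb5 itself (adjusted p = 0.0861). Its counts may be reads of Psmb5 RNA, so it need not be a separate change.

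H2-T3 lost its call without WT 2 (adjusted p = 0.0621) or WT 3 (0.0694), and Mir686 without WT 1, WT 2, QKO 1, QKO 2 or QKO 4 (adjusted p up to 0.108). Without WT livers 3 and 4, which held the acinar transcripts, 16 genes passed, 11 of them among the 15, and Dab1 (adjusted p = 0.0591) and H2-T3 (0.16997) did not. The other called genes were Msrb2, Msrb3 and 5 unnamed models with log2 changes of 2.03 to 4.76: Gm3375, Gm12338, Gm9967, 0610043K17Rik and Gm12798. Gm12798 lost its call without WT 1, WT 2, WT 3, QKO 1, QKO 2 or QKO 3 (up to 0.182). Within animal series 47 and within series 48, with 2 animals per group, 12 and 6 of the 15 passed. All 15 moved the same way there, which the choice of the genes on all 8 animals favours.

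**Figure D3:**
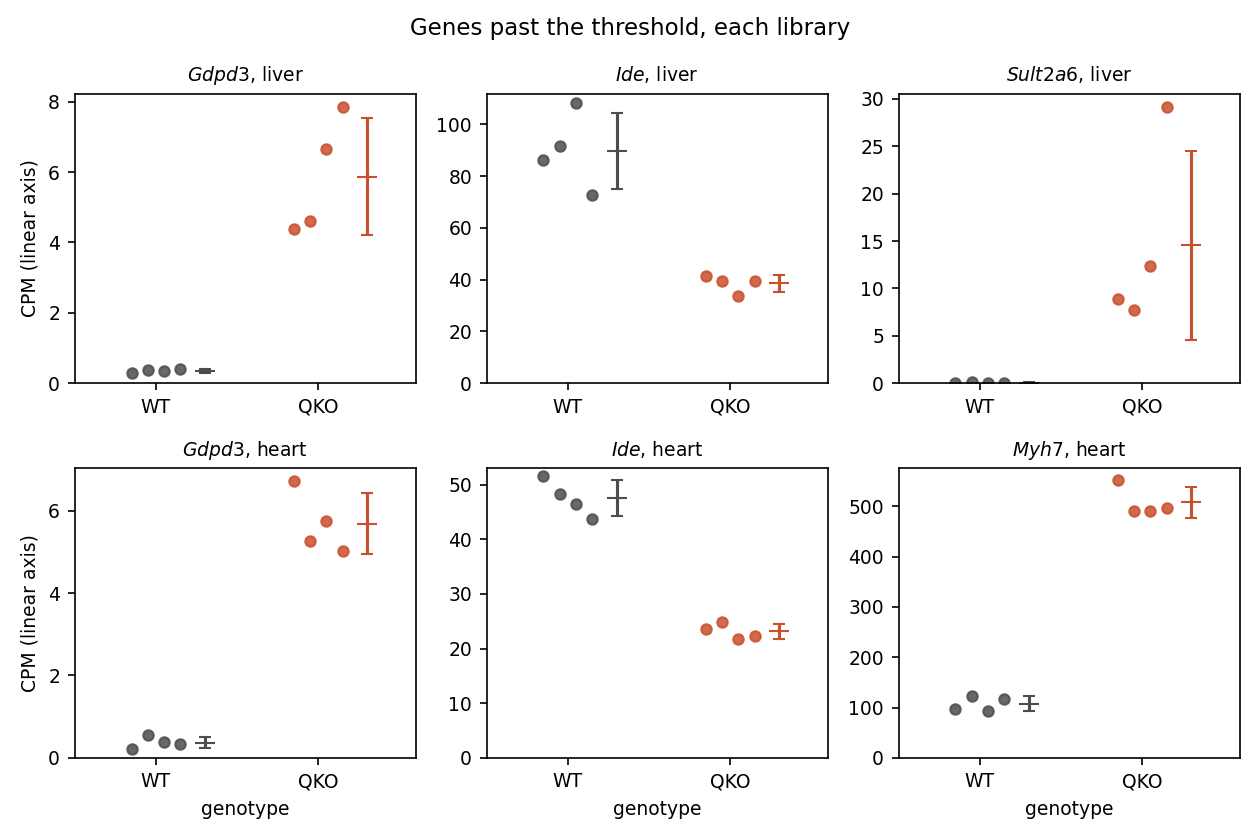
CPM (linear axis from 0) of Gdpd3 and Ide in liver and heart, Sult2a6 in liver and Myh7 in heart, with points for libraries and marks with bars for mean ± SD of 4. No WT library overlaps a QKO library in these panels. Relative to its mean, Sult2a6 is the most scattered, at 14.5 ± 9.92 CPM in QKO livers.

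Among gene groups in liver, red cell and unfolded protein response genes were lower by camera and immediate early genes higher, and no list was called with an estimated correlation. All 8 genes of the red blood cell list lay lower in QKO livers, with a median log2 change of -0.70 (camera adjusted p = 1.755e-09, and adjusted p = 0.319 with an estimated correlation). Summed, red cell transcripts stood at 621, 342, 262 and 400 CPM of the protein-coding count in WT livers 1 to 4. They stood at 252, 278, 319 and 276 CPM in QKO livers 1 to 4, so the groups overlapped. Over all genes 0 of them passed, while 4 did adjusted over the list alone: the globin genes Hba-a1 (-0.69), Hba-a2 (-0.74) and Hbb-bt (-0.77), and Alas2 (-0.50), the first enzyme of heme synthesis in red cells. Of the unfolded protein response list, 20 of 23 genes lay lower, with a median of -0.31 (camera adjusted p = 3.237e-09, and adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone 3 passed, the chaperone Hspa5 (-0.59), its cofactor Dnajb9 (-0.69) and Manf (-0.71), a factor induced by stress of the endoplasmic reticulum, and 0 did over all genes. Of the immediate early genes, which respond within minutes to growth signals, 22 of 23 lay higher, with a median of 0.42 (camera adjusted p = 3.438e-08, and adjusted p = 0.509 with an estimated correlation). Nr4a1, an orphan nuclear receptor, was the 1 gene past the threshold adjusted over the list alone, at 2.14; QKO livers held 1.61 ± 1.49 CPM, and without QKO 2 the change was 1.26. These 3 lists kept their camera calls without any 1 library and without WT livers 3 and 4, but the median of the unfolded protein response list was -0.19 without WT 3 and -0.17 without WT livers 3 and 4.

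Markers of other cell types moved with the libraries that held foreign transcripts. The pancreatic acinar list had a median of -6.97 over 4 of 4 genes (camera adjusted p = 3.168e-06, and adjusted p = 0.517 with an estimated correlation), and it followed WT livers 3 and 4, at 1602 and 478 CPM. Without these libraries its median was 0.14, and that of B and plasma cells, which was -1.06 over 11 of 11 genes, became 0.16. The adjusted p of the latter was 0.00286, and it was 0.969 without WT 3 alone (adjusted p = 0.823 with an estimated correlation). Cardiac fibroblast genes were lower in 10 of 11 (median -0.44, camera adjusted p = 0.00286, and adjusted p = 0.823 with an estimated correlation). Smooth muscle and pericyte genes were lower in 10 of 12 (median -0.17, camera adjusted p = 0.0246, and adjusted p = 0.761 with an estimated correlation). Genes of the extracellular matrix were lower in 28 of 38 (median -0.08) and those of the actin cytoskeleton in 25 of 30 (median -0.10), each at a camera adjusted p of 0.0246 and at adjusted p = 0.823 with an estimated correlation. These 4 groups lost their calls without WT 4, the library with 652 CPM of skeletal muscle transcripts, where the adjusted p was 0.299, 0.347, 0.806 and 0.552. The last 3 did so without QKO 3 as well (0.102, 0.466 and 0.262). Without WT livers 3 and 4 the median of the extracellular matrix list was 0.070. It was 0.026 without WT 4, -0.039 without QKO 3, and -0.12 to -0.18 without WT 1, WT 2, WT 3, QKO 2 or QKO 4. Without WT 4 the medians were -0.084 for cardiac fibroblast genes and -0.016 for actin genes. That of smooth muscle genes was -0.28 without WT 2, -0.28 without QKO 3 and -0.31 without QKO 4.

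Further liver lists passed the camera threshold as well. Proliferation genes were lower in 24 of 28 (median -0.19, adjusted p = 0.00286, and adjusted p = 0.761 with an estimated correlation) and heat shock genes in 20 of 22 (median -0.12, adjusted p = 0.0110, and adjusted p = 0.823 with an estimated correlation). Without WT livers 3 and 4 both calls ended (0.0612 and 0.874), as they did without WT 4 (0.0754 and 0.323) and without QKO 4 for the first (0.0560) and QKO 1 for the second (0.250). The proliferation median was -0.12 without WT 4 and -0.29 without QKO 1, and that of heat shock genes -0.031 without QKO 1, -0.076 without WT 4 and -0.18 without QKO 4. Endothelial genes were higher in 16 of 18 (median 0.21, 0.14 without WT 4 and 0.11 without QKO 4, adjusted p = 0.00105, and adjusted p = 0.761 with an estimated correlation; 0.0912 without QKO 4). Genes of class II antigen presentation were higher in 7 of 10 (median 0.34, and 0.15 without WT 2, adjusted p = 0.0246, and adjusted p = 0.823 with an estimated correlation) and mesothelial genes in 10 of 11 (median 0.34, 0.63 without WT 4 and 0.22 without WT 1, adjusted p = 0.0246, and adjusted p = 0.720 with an estimated correlation). The antigen presentation call ended without WT 2 (0.462), QKO 3 (0.154) or QKO 4 (0.195), and the mesothelial call without WT 2 or any of QKO 1, 2 and 4 (up to 0.233). Glucuronosyl- and sulfotransferases, which conjugate drugs and steroids, were higher in 20 of 30 (median 0.16, adjusted p = 0.0315, and adjusted p = 0.823 with an estimated correlation). Their median was 0.075 without WT 3, 0.097 without WT 4 and -0.022 without both, and the call ended without WT 3, WT 4, QKO 2, QKO 3 or QKO 4 (up to 0.618).

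In all, 15 of 54 lists passed camera in liver, 5 higher and 10 lower, against 0 with an estimated correlation and 0 by fry. The numbers with an unadjusted p under 0.05 were 22, 4 and 4. Lists close to the function of the missing enzymes were not called in liver. The camera adjusted p was 0.394 for antioxidant enzymes, 0.607 for NRF2 targets, 0.0917 for glutathione S-transferases, 0.478 for selenoproteins and 0.106 for the methionine cycle, with medians of 0.02 to 0.07. The number of lists was 28 without WT 1 and 27 without WT 2. Without WT livers 3 and 4, 6 of the 15 kept their calls.

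The third question was which heart genes differed. Myh7, the slow beta-myosin heavy chain of the heart muscle fibre, rose 4.73-fold in QKO hearts, from 107 ± 14.8 to 507 ± 30.3 CPM (SD, n = 4). Its share of Myh6 and Myh7 together went from 2.203% to 7.87%. Gdpd3 rose 16.2-fold, from 0.371 ± 0.133 to 5.69 ± 0.747 CPM, and Ide fell from 47.5 ± 3.28 to 23.1 ± 1.41 CPM. Ppt1, a lysosomal enzyme that removes palmitate from proteins, rose from 11.05 ± 0.978 to 18.3 ± 1.04 CPM. Lcp1, an actin-bundling protein of leukocytes, fell from 7.57 ± 0.403 to 4.29 ± 0.585 CPM.

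Of 16974 genes tested in heart, 28 passed the threshold, 12 higher and 16 lower in QKO, and 1220 had an unadjusted p under 0.05 where chance would give 849. The log2 change was 2.24 for Myh7 (SE 0.10, adjusted p = 3.226e-08), 4.02 for Gdpd3 (SE 0.19, adjusted p = 5.053e-08), 0.72 for Ppt1 (SE 0.08, adjusted p = 4.628e-04), -1.04 for Ide (SE 0.07, adjusted p = 2.607e-06) and -0.83 for Lcp1 (SE 0.10, adjusted p = 0.00245). Mhrt, an RNA antisense to Myh7 that overlaps it, rose by 2.19 (SE 0.12, adjusted p = 2.115e-07). Hyi, a putative hydroxypyruvate isomerase annotated as a polymorphic pseudogene, rose from 0.562 ± 0.0982 to 1.47 ± 0.0701 CPM (log2 1.38, SE 0.18, adjusted p = 0.00431). Complement C4b fell by 1.20 (SE 0.21, adjusted p = 0.0468), the tyrosine kinase Ptk2b by 1.09 (SE 0.19, adjusted p = 0.0355), Tceanc2 by 0.77 (SE 0.09, adjusted p = 0.00211) and Slc25a37, the mitochondrial iron carrier mitoferrin, by 0.70 (SE 0.12, adjusted p = 0.0263). Natriuretic peptides, markers of cardiac stress, did not pass, with 0.60 for Nppa (adjusted p = 0.738) and -0.49 for Nppb. Skeletal actin Acta1 had 1.04 (adjusted p = 0.314) and Myh6, the alpha-myosin heavy chain, 0.31.

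In the fit of all 16 libraries Myh7 (adjusted p = 1), Mhrt (0.0781) and C4b (0.0781) did not pass. That fit gives a gene the same dispersion in both tissues. Myh7 had 313 counts in WT liver 4, which held cardiomyocyte transcripts, and 8, 1 and 6 in the other WT livers. Mhrt had 44 counts there and 1 in each of the others. For Myh7 and Mhrt the result of that fit is thus no measure of the heart libraries alone. C4b lost its call without WT 1, WT 3, WT 4, QKO 2, QKO 3 or QKO 4 (up to 0.172), Ptk2b without each library except QKO 3 (up to 0.133), and Slc25a37 without each library except QKO 1 (up to 0.118). Without the heart libraries of replicate 4, which held little nuclear ribosomal RNA, 22 genes passed, 20 of them among the 28. Those that lost their call include Msrb1 (adjusted p = 0.183) and Hyi (0.0505). The other called genes were the targets, 5 unnamed models with log2 changes of 1.47 to 4.58, and 8 genes outside the naming rule. Among these, Piwil2, a germline gene, had 72 counts in WT and 5 in QKO, Ripk4 had 21 and 136, and Esd, Sucla2, Fndc3a, Btaf1 and Vwa8 had log2 changes of -0.58 to -0.40. Of the last 5, Vwa8 kept its call without any 1 library, and each of the others lost it without 6 or 7 of the 8 libraries (up to 0.132). Within animal series 47 and within series 48, 20 and 16 of the 28 passed. All 28 moved the same way there, which the choice of the genes on all 8 animals favours.

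Heart genes past the threshold lay together on the chromosomes. Besides the targets themselves, 12 of 305 genes tested within 20 Mb of Msra passed, against 11 of 15638 genes far from every Msr gene (Fisher's exact test, odds ratio 58.0, 95% interval 23.3 to 147, two-sided p = 2.171e-15). They include Myh7, Mhrt, Ptk2b, Slc25a37 and Lcp1, and 3 were higher and 9 lower. In liver 2 of 324 genes tested there passed, Cebpe and Mir686. In heart 1 of 475 genes near Msrb1, 0 of 377 near Msrb2 and 0 of 175 near Msrb3 passed in edgeR. Of the 36 genes past the threshold in either tissue, 15 lay on chromosome 14 between 54.6 and 79.2 Mb and 6 on chromosome 4 between 101 and 122.9 Mb, among them Dab1, Hyi, Ppt1 and Tceanc2. C4b and H2-T3 lay within 20 Mb of Msrb1.

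**Figure D4:**
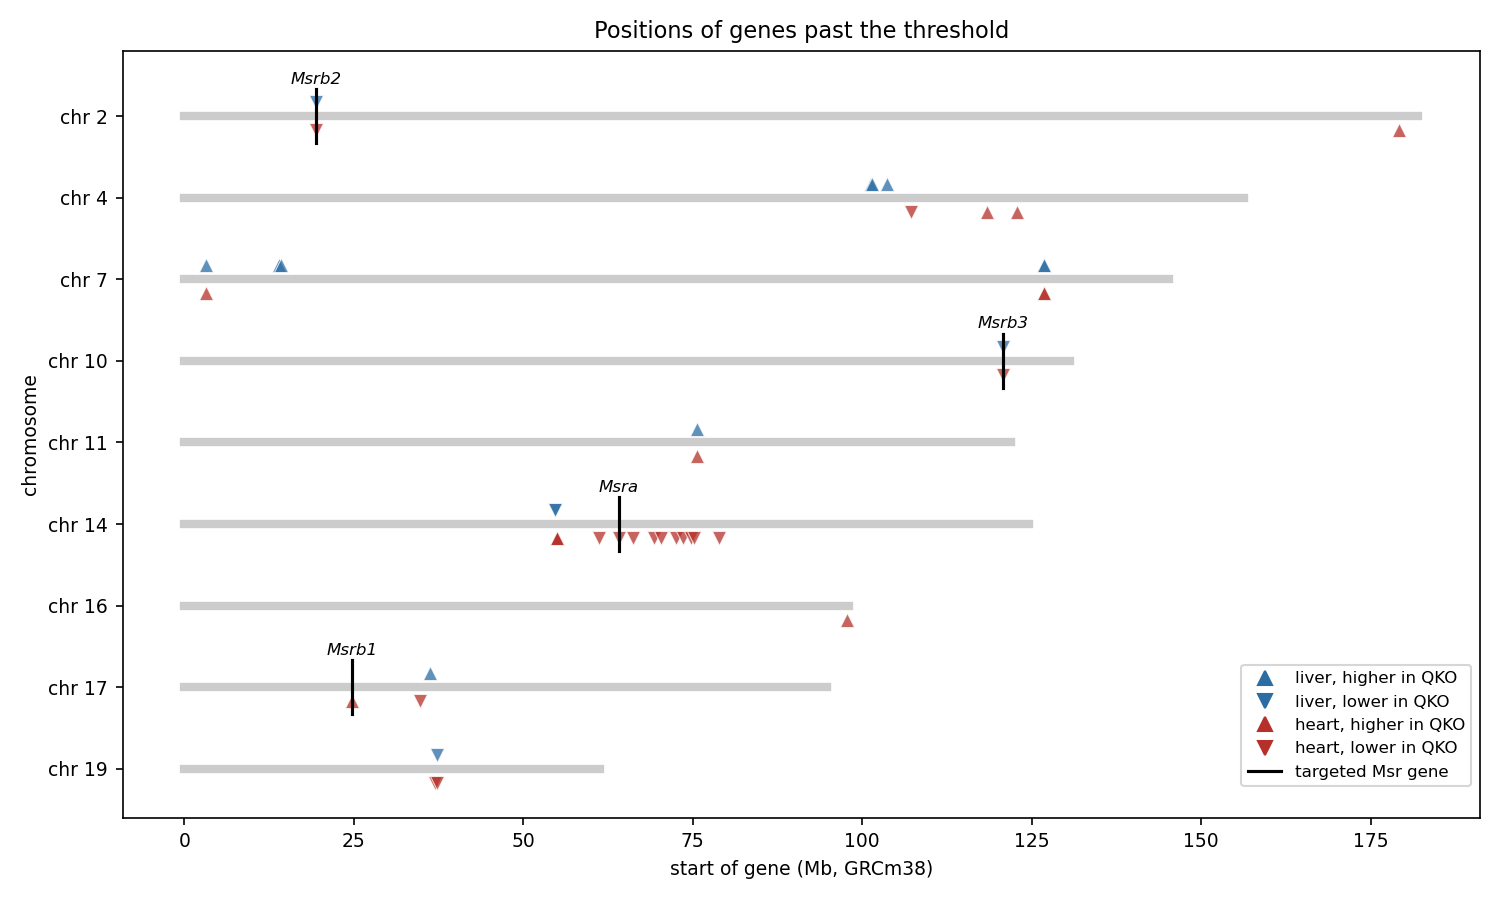
Start positions (Mb, GRCm38) of the 36 genes past the threshold in liver (blue, above each line) or heart (red, below it) on 9 chromosomes, with upward triangles for genes higher in QKO, downward ones for genes lower and black bars for the Msr genes. Of these genes 15 lie on chromosome 14, around Msra, and 6 on chromosome 4.

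Among gene groups in heart, macrophage and complement genes were lower by camera and nuclear genes of the respiratory chain higher, and no list was called with an estimated correlation. Of the macrophage list, 14 of 16 genes lay lower in QKO hearts, with a median of -0.37 (camera adjusted p = 2.037e-11, and adjusted p = 0.316 with an estimated correlation). Over all genes 0 passed, and 8 did adjusted over the list alone, among them the complement receptor Vsig4 (-1.18), the lysosomal protein Cd68 (-0.68), the growth factor receptor Csf1r (-0.46) and the mannose receptor Mrc1 (-0.40). Cytokine and chemokine genes were lower in 14 of 20 (median -0.18, camera adjusted p = 0.00492, and adjusted p = 0.319 with an estimated correlation), where the monocyte chemokine Ccl12 (-1.71) and the alarmin Il33 (-0.93) passed adjusted over the list alone. The cytokine median was -0.040 without QKO 4 and -0.084 without QKO 2. Genes of the acute phase and complement were lower in 24 of 27 (median -0.59, -0.94 without QKO 1, -0.92 without WT 4 and -0.39 without WT 1, camera adjusted p = 4.838e-10, and adjusted p = 0.432 with an estimated correlation). C4b passed over all genes, and adjusted over the list alone members that passed include C3 (-0.83) and the protease inhibitor Serpina3n (-1.02). Hepatocytes also express many of these genes, and their transcripts ran from 276 to 1228 CPM in WT hearts and from 305 to 737 CPM in QKO hearts. Nuclear genes of oxidative phosphorylation were higher in 80 of 81 (median 0.10, camera adjusted p = 2.741e-08, and adjusted p = 0.569 with an estimated correlation), while mitochondrially encoded ones were lower in 9 of 13 (median -0.26, adjusted p = 0.0427, and adjusted p = 0.569 with an estimated correlation). Without QKO 4 the median of the nuclear genes was 0.058. The call for mitochondrially encoded genes ended without WT 1, WT 2, WT 3, QKO 1 or QKO 3 (up to 0.409), and their median was -0.081 without WT 3, -0.16 without QKO 3 and -0.40 without WT 4. Genes of the unfolded protein response were lower in 20 of 22 (median -0.17, camera adjusted p = 1.901e-05, and adjusted p = 0.403 with an estimated correlation), with Dnajc3 (-0.35), a cochaperone, past the threshold adjusted over the list alone.

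Muscle and housekeeping groups moved by small amounts. All 16 cardiomyocyte genes lay higher (median 0.10, and 0.067 without QKO 4, camera adjusted p = 0.00598, and adjusted p = 0.569 with an estimated correlation), as did 31 of 41 genes of calcium handling and excitation (median 0.08, adjusted p = 0.00321, and adjusted p = 0.569 with an estimated correlation; 0.0587 without QKO 1, and median 0.048 without WT 4). Of the latter the potassium channel Kcnj2 (0.36) passed adjusted over the list alone. The 3 skeletal muscle genes tested were higher (median 0.27, adjusted p = 0.0105, and adjusted p = 0.403 with an estimated correlation), with Acta1 and creatine kinase Ckm (0.27) past the threshold adjusted over the list alone. For cardiac stress genes camera gave a rise (adjusted p = 0.0427, and adjusted p = 0.569 with an estimated correlation), but the median was -0.077 and the mean 0.07, and the call ended without WT 1 (0.205), WT 4 (0.483), both libraries of replicate 4 (0.425) or the genes near the Msr loci (0.984), and with the animal series as a term (0.0512). Without WT 3 the median was 0.039, and without QKO 1 it was -0.032. Proteasome genes were higher in 31 of 38 (median 0.08, adjusted p = 0.00272, and adjusted p = 0.569 with an estimated correlation), although Psmb5 (-0.42) was the 1 member past the threshold adjusted over the list alone. Genes of cytosolic ribosomal proteins were higher in 67 of 80 (median 0.05, adjusted p = 0.00282, and adjusted p = 0.811 with an estimated correlation), a call that ended without WT 3 (0.118), QKO 4 (0.834) or both libraries of replicate 4 (0.537) and with the nuclear ribosomal RNA share as a covariate (0.345). Their median was 0.0054 without QKO 4, 0.030 without WT 3, 0.083 without WT 2 and 0.088 without QKO 1.

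Matrix, surface and nerve cell markers were lower. Genes of the extracellular matrix lay lower in 31 of 41 (median -0.09, -0.17 without WT 4 and -0.16 without QKO 1, adjusted p = 7.052e-04, and adjusted p = 0.569 with an estimated correlation), with the collagen Col14a1 (-0.54) past the threshold adjusted over the list alone. All 7 mesothelial genes lay lower (median -0.55, and -0.86 without QKO 1, adjusted p = 0.00321, and adjusted p = 0.403 with an estimated correlation), with Upk3b and Muc16 past it adjusted over the list alone. Schwann cell and neuron genes lay lower in 7 of 9 (median -0.40, adjusted p = 0.0309, and adjusted p = 0.569 with an estimated correlation). This last call ended without each library except WT 3 and QKO 1 (up to 0.105) and with the nuclear ribosomal RNA share as a covariate (0.0724). NRF2 targets, genes of the response to oxidants, lay lower in 26 of 36 (median -0.09, adjusted p = 0.0344, and adjusted p = 0.403 with an estimated correlation), and the call ended without WT 4 (0.161) or QKO 1 (0.0919).

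Groups of liver genes were lower in QKO hearts, and so was the amount of hepatocyte transcripts, which differed between hearts of 1 group as well. It stood at 1228, 870, 627 and 276 CPM in WT hearts and at 737, 502, 402 and 305 in QKO hearts. All 14 hepatocyte genes lay lower (median -0.63, camera adjusted p = 3.937e-04, and adjusted p = 0.569 with an estimated correlation), as did 30 of 33 cytochrome P450 genes (median -0.62, adjusted p = 3.937e-04, and adjusted p = 0.569 with an estimated correlation). Glucuronosyl- and sulfotransferases were lower in 19 of 20 (median -0.45, adjusted p = 0.00400, and adjusted p = 0.671 with an estimated correlation). Bile acid genes were lower in 14 of 20 (median -0.26), periportal genes in 11 of 13 (median -0.34) and female-biased liver genes in 13 of 17 (median -0.30), with camera adjusted p of 0.0246, 0.0246 and 0.0360 and adjusted p = 0.569 with an estimated correlation for each. All 6 calls ended without WT 1, the heart with the most hepatocyte transcripts, where the adjusted p was 0.184, 0.153, 0.264, 0.603, 0.557 and 0.446 and the medians -0.25, -0.16, -0.28, -0.066, -0.15 and -0.15. Transferases and periportal genes lost theirs also without WT 2 (0.171 and 0.165) or QKO 4 (0.0656 and 0.109), and female-biased genes without WT 2, QKO 1, QKO 2 or QKO 4 (0.0582 to 0.125). With the nuclear ribosomal RNA share as a covariate the calls for transferases (0.117), bile acid genes (0.0724), periportal genes (0.163) and female-biased genes (0.151) ended. Without WT 4, the heart with the fewest hepatocyte transcripts, the 6 medians were -0.998, -0.96, -0.75, -0.64, -0.65 and -0.49. The hepatocyte median was -0.40 without QKO 4, the transferase median -0.70 without QKO 1, -0.26 without WT 2 and -0.25 without QKO 4, the female-biased median -0.49 without WT 2 and -0.18 without QKO 4, and the bile acid median -0.41 without QKO 2, -0.14 without WT 2 and -0.13 without QKO 4.

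In all, 22 of 51 lists passed camera in heart, 7 higher and 15 lower, against 0 with an estimated correlation and 0 by fry. The numbers with an unadjusted p under 0.05 were 24, 6 and 10. With the animal series as a term 21 of the 22 passed, and without the libraries of replicate 4, 18 did. With the share of nuclear ribosomal RNA as a covariate 16 of the 22 passed, and without WT 1, 13 did. Antioxidant enzymes (adjusted p = 0.421), glutathione S-transferases (0.709), selenoproteins (0.714) and the methionine cycle (0.743) were not called in heart.

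**Figure D5:**
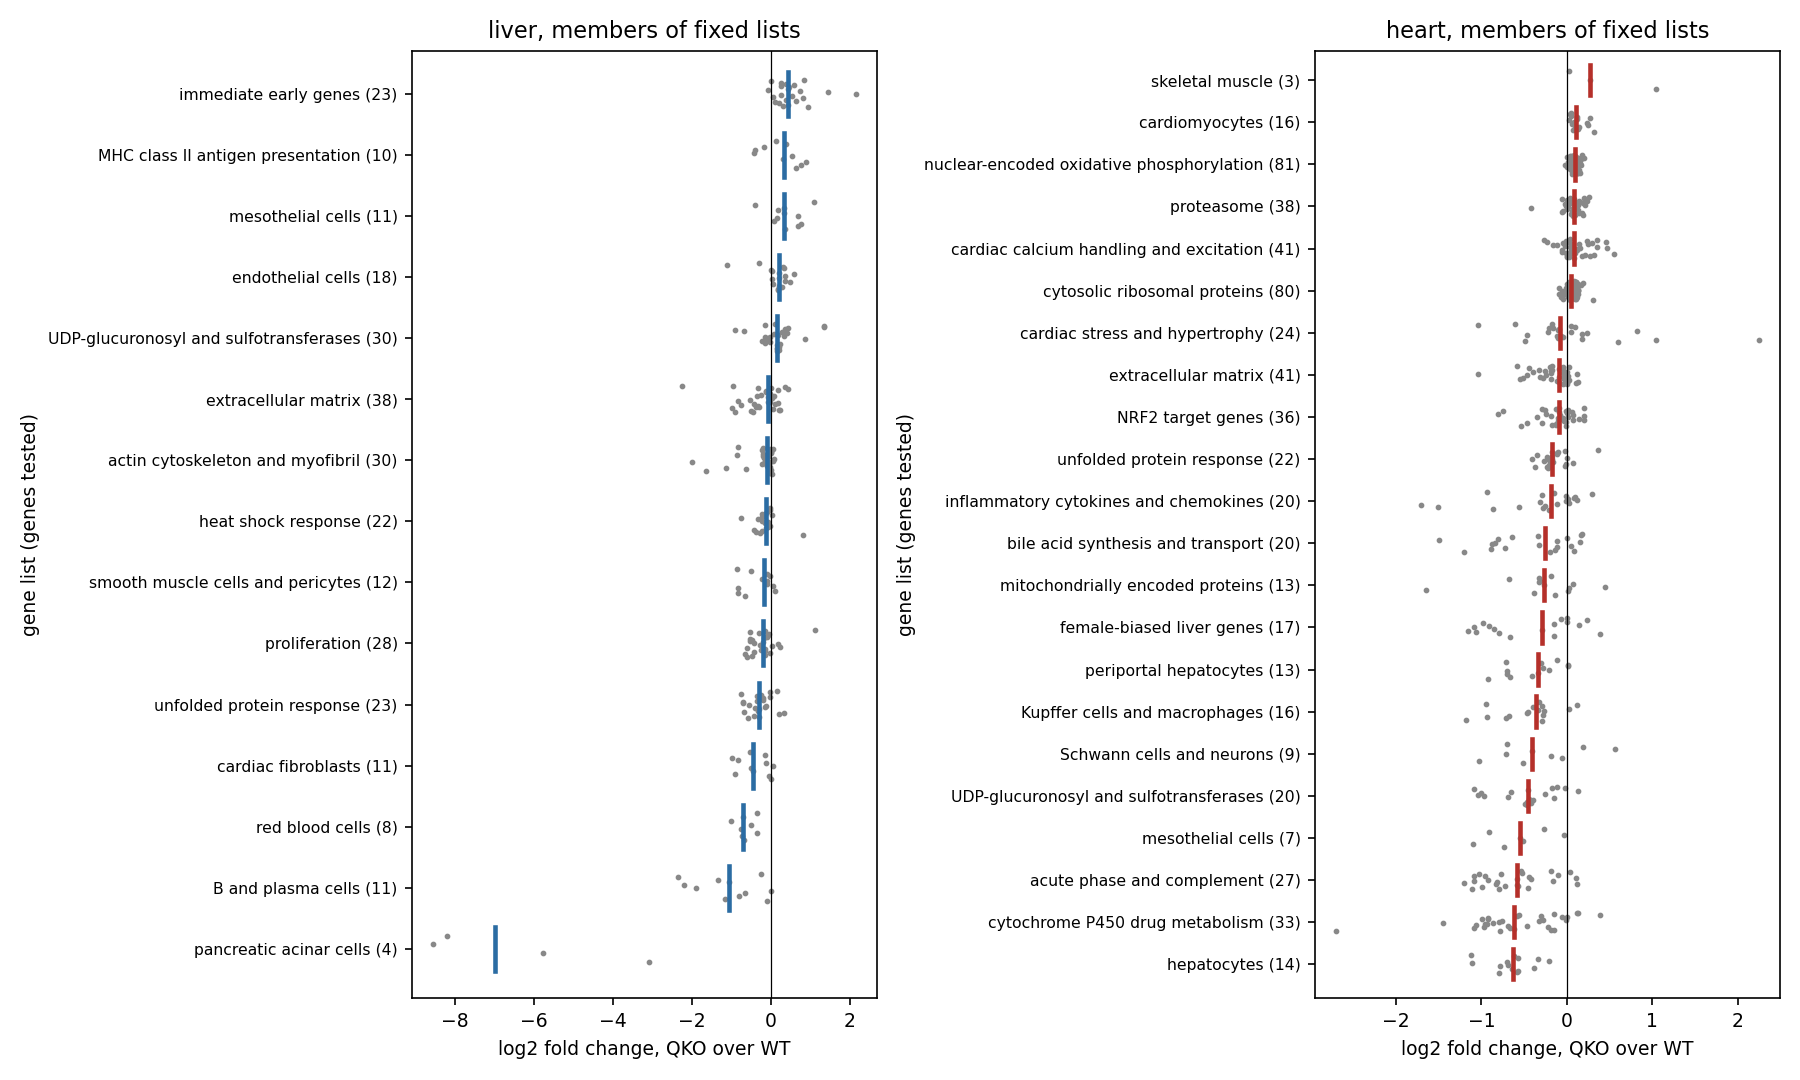
Log2 fold change (QKO over WT) of the tested members of each list past the camera threshold, 15 in liver and 22 in heart, with grey points for genes, coloured bars for medians and the number of genes tested in brackets. Medians run from -6.97 (pancreatic acinar cells) to 0.42 (immediate early genes) in liver; all 37 calls were lost with an estimated correlation.

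The fourth question was which genes changed in both tissues. Gdpd3, Ide, Msrb2 and Msrb3 did, each in the same direction, together with the pseudogenes Gm3375 and Gm12338 and with Gm9967, a transcript that overlaps Gdpd3. Gm3375 rose 25.5-fold in liver, from 0.468 ± 0.135 to 12.2 ± 1.29 CPM (SD, n = 4), and by 4.58 on the log2 scale in heart. The heart effect minus the liver effect was -0.05 (SE 0.32) for Gdpd3 and 0.17 (SE 0.17) for Ide, and neither passed the interaction test. Of 15436 genes tested in both tissues, 7 passed in both with the same direction, 4 higher and 3 lower, where chance would give 0.00713. With opposite directions 0 passed. The chance value takes the tissues as independent, although the same animals gave both, and Msrb2 and Msrb3 differ by design. Hyi passed in heart alone, and its liver value was 1.26 (adjusted p = 0.0952), from 28.7 ± 8.63 to 68.7 ± 14.96 CPM. Gm12338 lost its liver call without WT 2 (0.0832) or WT 3 (0.0883) and its heart call without WT 3 (0.0578).

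The last question was which genes responded differently in heart and liver. Ripk4, a kinase of epithelial differentiation, was the 1 gene of 19587 past the threshold. It rose from 0.0737 ± 0.0355 to 0.511 ± 0.0862 CPM in heart (SD, n = 4) and stood at 8.44 and 9.12 CPM in liver. The heart effect minus the liver effect was 2.52 (SE 0.29, adjusted p = 0.00216), from 2.65 (SE 0.37) in heart and 0.11 (SE 0.13) in liver. Before adjustment 784 genes had a p under 0.05, where chance would give 979. With the animal as a block 0 genes passed in edgeR (742 with an unadjusted p under 0.05), limma-voom called 0 (551 unadjusted) and DESeq2 called 13. Ripk4 was named after its values were seen, since its CPM in heart lay under the naming minimum of 1.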

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

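The tests of skeletal muscle transcripts and of the neighbours of Myh7 were chosen only after the result was seen. Each group of 4 libraries was checked for a library far from the rest, by its gap to the nearest other library as a share of the range of the group (Dixon's 95% critical value). Of 94 groups 12 exceeded it, where 1 in 20, or 4.70 groups, would by chance.

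Several far values concerned the content of a library. QKO heart 4 had 28.1 M protein-coding counts against 8.90 M to 11.5 M (share 0.863). Acinar transcripts stood at 8.06 CPM of the protein-coding count in WT heart 3 against 0.606 to 1.32 (0.904). Skeletal muscle transcripts stood at 652 CPM in WT liver 4 against 1.40 to 2.39 (0.998), and at 48.7 in QKO liver 2 against 2.94 to 7.30 (0.905). Cardiomyocyte transcripts stood at 920 CPM in WT liver 4 against 73.3 to 158 (0.900), and hepatocyte transcripts at 117583 in WT liver 2 against 103935 to 105976 (0.8505).

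Others concerned single genes. Msrb1 stood at 142 CPM in QKO liver 3 against 86.4 to 94.4 (0.855), and without that library its liver change was -0.58. Nnt stood at 40.9 CPM in QKO liver 2 against 34.4 to 35.5 (0.832) and Mir686 at 10.1 CPM in QKO liver 3 against 7.71 to 8.10 (0.837). Cebpe had its 1 count in QKO liver 1, at 0.0156 CPM against 0 (share 1). Mhrt stood at 141 CPM in QKO heart 1 against 102 to 108 (0.841). Ripk4 was listed because its genotype effect differed between the tissues by 2.52 on the log2 scale in the interaction test, a call that limma-voom and the animal block did not give.

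Myh7 stood at 553 CPM in QKO heart 1 against 490 to 497 in the other QKO hearts (0.885), all above the WT hearts. Skeletal muscle in the QKO samples is argued against, since 9 skeletal genes together rose by 0.350 CPM (SD 0.313, from 2.06 to 2.41) beside 400 CPM for Myh7; this sum replaced a planned median because 1 of the 9 genes was tested. A cardiac stress programme that raises most of its genes is argued against too, as the other 23 tested members of that list had a median of -0.091 (SD 0.44). A median cannot exclude a partial one. Acta1 (1.04) passed adjusted over the list alone, while 14 of the 24 members lay lower. DNA of another strain around Msra, carried along in breeding, may explain the rise, since Myh7 lies 9.13 Mb from Msra, but apart from Mhrt and Gm29015, which overlap it and passed, 0 of the 129 other heart genes within 5 Mb did (edgeR; upper 95% bound of the odds ratio 20.99, Fisher's exact p = 1), while in liver Cebpe (-7.74) and Mir686 (-1.07), within 5 Mb as well, passed. With so few calls this cannot be told apart from an effect of Msr loss on the heart, which stays open and untested.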

How the results depend on the processing

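Added after the result was seen were the fits of protein-coding genes alone, with a robust dispersion, without the acinar or replicate 4 libraries and with the ribosomal RNA covariate, and for the lists the scalings and the series term. Of the alternatives for single genes named, the 4 Msr genes left out, 2202 kept their side of the threshold, 119 lost the call and 72 gained one. Many of these genes were not called as reported and could not lose a call, so the 2202 do not measure how stable the calls were. Among the called values 0 changed sign, while uncalled ones did so (Sult2a1 in liver, -0.37 without QKO 4). For lists 569 kept, 149 lost and 6 turned. The cause was not tested unless given here.

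In liver 15 genes passed, against 50 with DESeq2, 44 with all 16 libraries in 1 fit, and, with fewer genes tested, 9 without genes near the Msr loci and 9 among protein-coding genes. In heart 28 passed, against 64 with DESeq2, 102 with no count filter, 15 past a fold of 1.3, 16 with all 16 libraries in 1 fit, 11 without genes near the Msr loci, and 18 to 25 with 1 library left out (18 without QKO 2 or QKO 4). The replicate number as a block gave 16 genes in liver and 50 in heart. The labels do not present the number as a pairing of animals. It does follow the animal series, and the replicate 4 hearts of WT and QKO resembled each other (correlation 0.331). The difference between tissues, 1 gene, gave 13 with DESeq2, 0 with limma-voom, 2 with no filter, 0 with the animal block, 3 with the series term and 1 to 2 with 1 library left out (2 without WT 4). In both tissues 7 passed, against 13 with DESeq2 and 4 among protein-coding genes.

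List calls, 15 in liver and 22 in heart, went to 0 in each with an estimated correlation and 0 in each by fry, tests that allow for related genes. Leaving out 1 library gave 12 to 28 in liver (28 without WT 1, 27 without WT 2). Without the acinar libraries medians became -0.022 (transferases), 0.070 (extracellular matrix), 0.16 (B and plasma cells) and 0.14 (acinar cells), opposite in test direction. B and plasma cells ran from -1.17 to 0.093 with 1 library left out, 0.093 without WT 3. Cardiac stress genes in heart turned in test direction without Myh7 and other genes near the Msr loci (median -0.077).

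Msra in liver passed with DESeq2 (-0.71) and all 16 libraries (-0.71). Msra in heart did not pass with limma-voom (-0.49), a fold of 1.3 (-0.52) or all 16 libraries (-0.52), and ran from -0.57 to -0.48 with 1 library left out. Msrb1 in heart did not pass with a fold of 1.3 (0.48), all 16 libraries (0.47), replicate 4 left out (0.37) or the ribosomal RNA covariate (0.44), and ran from 0.42 to 0.53. Simulated changes of a fold of 2 were recovered at 40.3% in liver and 59.7% in heart.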

Other observations

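The tests of copy number at Ide and of clusters away from the Msr loci, the counts of splits without the Msr genes, and all values for the animal series as a comparison of its own, were chosen only after the result was seen.

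Hearts of animals numbered 48 differed from those numbered 47 in 114 of 16974 genes tested by edgeR. Nr4a1, an immediate early nuclear receptor, was lower in series 48 by a log2 change of -2.81 (SE 0.31, adjusted p = 0.00124), as were the kinase Sik1 (-1.06), the insulin receptor substrate Irs2 (-1.27), the transcription factor Prox1 (-0.69) and the cell death gene Bcl2l11 (-0.97). Palm (0.73) and Amd1 (0.58), an enzyme of polyamine synthesis, were higher. Of the 114, 44 were higher and 70 lower in series 48, and 0 of them were among the genotype calls. In liver 0 of 17738 genes passed in edgeR for the same split, but 2753 had an unadjusted p under 0.05 where chance would give 887. In heart 1981 did, where chance would give 849. The lack of liver calls therefore does not show that livers of the series were alike. WT heart 4 and QKO heart 4, at 7.87% and 0.148% nuclear ribosomal RNA, are both of series 48. Without these hearts 7 genes passed, 6 of them among the 114, and Bcl2l11 (-1.02, adjusted p = 0.0953) and Amd1 (0.51, 0.114) did not. The log2 changes of Bcl2l11 and Amd1 were about as large with fewer libraries, as were those of Sik1 (-0.98), Prox1 (-0.67) and Palm (0.74). Those of Nr4a1 (-2.14) and Irs2 (-0.99) were smaller in size. Calls lost with fewer libraries do not tell whether the content of WT heart 4 and QKO heart 4 matters.

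Gene groups also differed between the series in heart. In series 48 interferon response genes were higher in 45 of 46 (median 0.32, camera adjusted p = 7.663e-12, and adjusted p = 0.334 with an estimated correlation) and those of class II antigen presentation in 8 of 8 (median 0.41, adjusted p = 1.450e-05, and adjusted p = 0.334 with an estimated correlation). Cholesterol synthesis genes were lower in 23 of 25 (median -0.27, adjusted p = 6.807e-07, and adjusted p = 0.292 with an estimated correlation). Hepatocyte genes were lower in 14 of 14 (median -1.20, adjusted p = 2.558e-20, and adjusted p = 0.292 with an estimated correlation), as were 28 of 33 cytochrome P450 genes (median -1.07, adjusted p = 6.926e-15, and adjusted p = 0.292 with an estimated correlation). Without WT heart 4 and QKO heart 4, 10 of the 24 lists past the camera threshold stayed past it in the same direction, among them these 5, with medians of 0.15, 0.43, -0.20, -0.68 and -0.57 (adjusted p = 0.640 with an estimated correlation for each).

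The genotype was compared with the other ways to split the 8 animals into 4 and 4, 35 splits in all with the real one. In liver 1 split, the real one, gave as many genes (real 15, or 13 without the 4 Msr genes, highest other 11). This argues against chance but does not exclude it, as 35 splits are few and another came near. For genes shared by both tissues 1 split gave as many (real 7, highest other 0), but Msrb2 and Msrb3 among them differ by design. Without the Msr genes 1 split gave the 5 that remain (highest other 0). This argues against chance for these but, with 35 splits, does not exclude it. Gdpd3 and Gm9967 among them overlap. In heart 3 splits gave 28 genes or more, or 24 without the Msr genes (highest other 114), so chance cannot be excluded by this count. The split with 114 is that of the animal series, which points to a structure of the samples. Another, with 77 genes, set WT hearts 1, 2 and 3 and QKO heart 1 against the rest. Those hearts held the most nuclear ribosomal RNA, 41.2% to 60.2% against 38.4% or less. Among splits with 2 animals of each series per group, like the genotype, the highest other gave 2 genes. That restriction was chosen after the result was seen. With the series as a term all 28 were called among 42. For the difference between tissues 5 splits gave 1 gene or more (highest other 7), so chance cannot be excluded.

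Genes past the threshold lay near the Msr loci more often than elsewhere in heart, with an odds ratio of 13.997 (95% interval 5.77 to 34.6; 13 of 1332 genes within 20 Mb), 12 of them at Msra, 1 at Msrb1 and 0 in edgeR at Msrb2 or Msrb3, and the lower bound of 5.77 argues against an effect of Msr loss that is blind to position as the whole account. In liver the odds ratio was 3.53 (Fisher's exact p = 0.0761; 3 of 1391 genes) with a lower bound of 0.624, and at Msra alone 10.14 (1.08 to 47.9; p = 0.178 without overlapping genes), so neither account is excluded there. DNA of another strain kept around Msra may therefore explain part of the heart calls. Away from the loci 16 called genes formed 10 pairs within 10 Mb, where the highest of 10000 random sets was 9. Gm9967, Gm12798, Sult2a4 and Btaf1 were then left out as overlapping, paralogous or close neighbours of another called gene. The other 12 formed 4 pairs (median of random sets 0, permutation p = 0.0115), all of them on chromosome 4. They lay among 0610043K17Rik, Dab1 and Tceanc2, and between Hyi and Ppt1. Further strain DNA on chromosome 4 may explain them. No genotypes were measured, and genes beyond these clusters stay open to an effect of Msr loss.

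Ide fell to less than 50% of the WT level in both tissues. A copy number difference of the segment with Ide and Fgfbp3 is a candidate explanation: Fgfbp3, its neighbour, had a log2 change of -0.94 (SE 0.55) in liver and -1.15 (SE 0.37, unadjusted p = 0.00752) in heart, although neither passed after adjustment. The genes within 2 Mb outside the segment had medians of 0.02 (27 genes) and -0.09 (21 genes), and 0 of them passed in edgeR. The 5 and 4 tested genes between Fgfbp3 and Ide had medians of 0.13 and -0.03, but Btaf1 among them fell in heart (-0.46, adjusted p = 0.0242) and had -0.41 in liver, so the extent of such a segment stays open. DNA was not measured, and an effect of Msr loss on Ide stays open and untested.

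With the share of nuclear ribosomal RNA as a covariate 23 of the 28 heart calls passed. Without WT livers 3 and 4, which held acinar transcripts, 6 of the 15 liver lists kept their calls and 4 turned in test direction. The 3 examined here kept theirs, those of red blood cells (median -0.75), the unfolded protein response (-0.17) and immediate early genes (0.70).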
